A study of Pimephales promelas with 12 samples.

How the data were processed

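Gene expression was measured in whole fathead minnow (Pimephales promelas) larvae after a 48-h static exposure to NQ. Each of the 12 arrays held the RNA of 1 replicate beaker, pooled from 4 of its 10 larvae, with 200 ng of total RNA labelled with Cy3, per the labels' protocols. There were 4 arrays each for the control, 20.7 mg/L and 2640 mg/L groups. The bioassay ran 9 concentrations including the control, and the other concentrations were not analysed here. The replicates are separate beakers per the labels, so the spread between them includes biological variation between pools of larvae.

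The arrays are 1-colour Agilent arrays, and the deposited scanner values are spot intensities on a linear scale that the authors obtained with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal used here was already background-subtracted and detrended by that software, per the file headers. The same deposited files carry other columns holding quality flags, which mark non-uniform spots, population outliers, saturated spots and spots well above background. No spot of a fish probe was saturated on any array. Each array holds 61053 such spots for 49849 probes (41517 with 1 spot, 7973 with 2 and 359 with 10), and its 1319 control spots were left out of all tests of probes.

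The authors' deposited value table holds log2 values of the same arrays. Set against the scanner signals, its values were the log2 processed signal after subtraction of the array's 75th percentile and of each probe's median over the 12 arrays, with correlations of 0.99998 or more for probes with 1 spot. Its scale, centring and direction are thus known from this comparison. Its column medians were 0.013, 0.0188, -0.0133 and -0.0159 in control replicates 1 to 4, 0.00215, 0.0128, 0.00393 and 0.045 at 20.7 mg/L, and 0.0809, -0.0428, -0.0255 and -0.0302 at 2640 mg/L. It was used only as an alternative.

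From the scanner values, spots flagged as non-uniform or as population outliers were left out, spots of a probe were averaged, and each array's 75th percentile of log2 processed signal was subtracted. A probe was kept if it was well above background on all 4 arrays of at least 1 group and had unflagged values on at least 2 arrays of each group. That left 31143 probes, with 562 probe values in the whole data set missing through flags. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 12 arrays with 1 term per group, 9 residual and 3.57 prior degrees of freedom. Tests were two-sided, and a probe was called changed at a Benjamini-Hochberg adjusted p under 0.05. The procedure was tested on simulated data with 200 changed probes among 31143 in 5 runs, for the comparison of 2640 mg/L with control. It recovered 25.2% of 2-fold and 77.6% of 4-fold changes, with 4.8 false calls per run on average. The simulated arrays were independent and of equal spread, unlike the real ones, so these rates may not hold for the real comparison. Array number and signal over background limit the precision.

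The probe identifiers carry no gene names in the files used here, and 0 of the 49849 matched the RefSeq gene table of assembly GCF_988280905.1. The 35 gene lists fixed before the data were examined, 12 of them lists of tissue markers, could therefore not be tested. The rule for named genes, the 12 largest rises and 12 largest falls among called genes with a symbol and 5 genes by smallest p where nothing was called, had nothing to apply to. In its place, 4 probes are given by identifier. They have the smallest p among probes higher and among probes lower at 2640 mg/L than in the control, and were picked after their values were seen.

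With 0 calls in each comparison, several measures were added after the data were seen. One was the number of probes at an unadjusted p under 0.05. Another was the mean correlation distance (1 minus Pearson's r) between arrays of different groups minus that within groups, with a one-sided exact permutation test over the 35 splits of 8 arrays. The relation between concentrations was set against simulated unchanged groups sharing the same controls. The 12 arrays came from 6 slides, and the place on the slide was taken from the scanner's array numbering.

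The alternatives were quantile normalization, median centring, normexp background correction (offset 50), the authors' table, other filters on dim probes, flagged spots kept, slide as a fixed or random block, the replicate number as a block, only the 2 groups compared, an intensity trend with a robust prior, array weights, other thresholds and leaving out each array. The files hold no mean spot signal, so normexp was run on median spot and background signals. Blocks for slide row and column, single slide columns, and combinations of these with array weights or a left-out array were added after the data were seen. Figures were drawn with matplotlib.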

Results

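Whole-larva transcript signals were measured in fathead minnow larvae held for 48 h in water with NQ (nitroguanidine, an ingredient of insensitive explosive formulations) at 20.7 or 2640 mg/L or in control water. These are the lowest and highest measured concentrations of the dose series, and each group had 4 arrays, each from a separate beaker. The 75th percentile of processed signal ranged from 555 to 862 intensity units between arrays, and 58.7% to 76.1% of probes lay well above background. Correlations between pairs of arrays ranged from 0.910 to 0.981. The median absolute log2 difference per probe was 0.25 to 0.49 between arrays of one group and 0.24 to 0.64 between arrays of different groups, against 0.20 between 2 spots of one probe on one array. The first principal component held 22.2% of the variance and set apart 2640 mg/L replicate 1, at 119.5, from the other 11 arrays, at -63.1 to 22.2. That array also had the widest spread of deviations, with an interquartile range of 0.84 on the log2 scale against 0.28 to 0.57 for the others.

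The comparison of the highest concentration with the control asks which transcripts differ after exposure to 2640 mg/L. No probe of 31143 passed limma's test at an adjusted p under 0.05, and 4287 (13.8%) had an unadjusted p under 0.05 where 1557 were expected by chance. Of these, 2250 were higher and 2037 lower at 2640 mg/L. Among all tested probes, 745 were at least 2-fold higher and 399 at least 2-fold lower, and the median SE of a log2 difference was 0.27. The arrays of the groups did not overlap for 2731 probes (8.77%), against 2.86% by chance.

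UF_Ppr_AF_117128 had the smallest p, with a log2 signal of -0.50 ± 0.41 in the control and -2.87 ± 0.42 at 2640 mg/L (SD, n = 4 each; limma log2 difference -2.36, SE 0.33, adjusted p = 0.107). UF_Ppr_AF_116657 differed by -1.27 (SE 0.18, limma adjusted p = 0.107), from 0.34 ± 0.31 to -0.93 ± 0.16 (SD, n = 4 each). SINGLET_31945 was higher at 2640 mg/L by 1.47 on the log2 scale (SE 0.25, limma adjusted p = 0.176), from -3.07 ± 0.36 to -1.60 ± 0.42 (SD, n = 4 each). UF_Ppr_AF_114698 was higher by 1.62 (SE 0.27, limma adjusted p = 0.176), from -4.85 ± 0.51 to -3.23 ± 0.33 (SD, n = 4 each), and was well above background on only 1 of the 4 control arrays, so that its control mean rests largely on signals near background. For each of these 4 probes, all 4 arrays at 2640 mg/L lay on one side of all 4 control arrays, although none was called. The probes were picked for that comparison, so the lack of overlap follows largely from the choice. Their mean at 20.7 mg/L lay between the other group means, at -1.29 ± 0.63 for UF_Ppr_AF_117128, -0.06 ± 0.03 for UF_Ppr_AF_116657, -2.06 ± 0.22 for SINGLET_31945 and -4.20 ± 0.34 for UF_Ppr_AF_114698 (SD, n = 4 each). With the other groups extreme by selection, a mean between them is likely without any effect at 20.7 mg/L. Slide 3 was the only slide with an array of both groups, 1 of each. There, on arrays that also served to pick the probes, the log2 differences between 2640 mg/L and control were -2.96, -1.49, 1.54 and 0.96 for UF_Ppr_AF_117128, UF_Ppr_AF_116657, SINGLET_31945 and UF_Ppr_AF_114698. With slide as a fixed block they were -2.29, -1.25, 1.43 and 1.28. That block takes 2640 mg/L replicates 1 and 3, each the only array from its slide, out of the comparison. Normexp background correction gave differences of -1.67, -1.25, 0.94 and 0.56. With array weights they were -2.45, -1.24, 1.21 and 1.87. All but SINGLET_31945 then passed (limma adjusted p = 0.0384, 0.0384 and 0.0492), and none passed with slide column as a block as well.

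**Figure D1:**
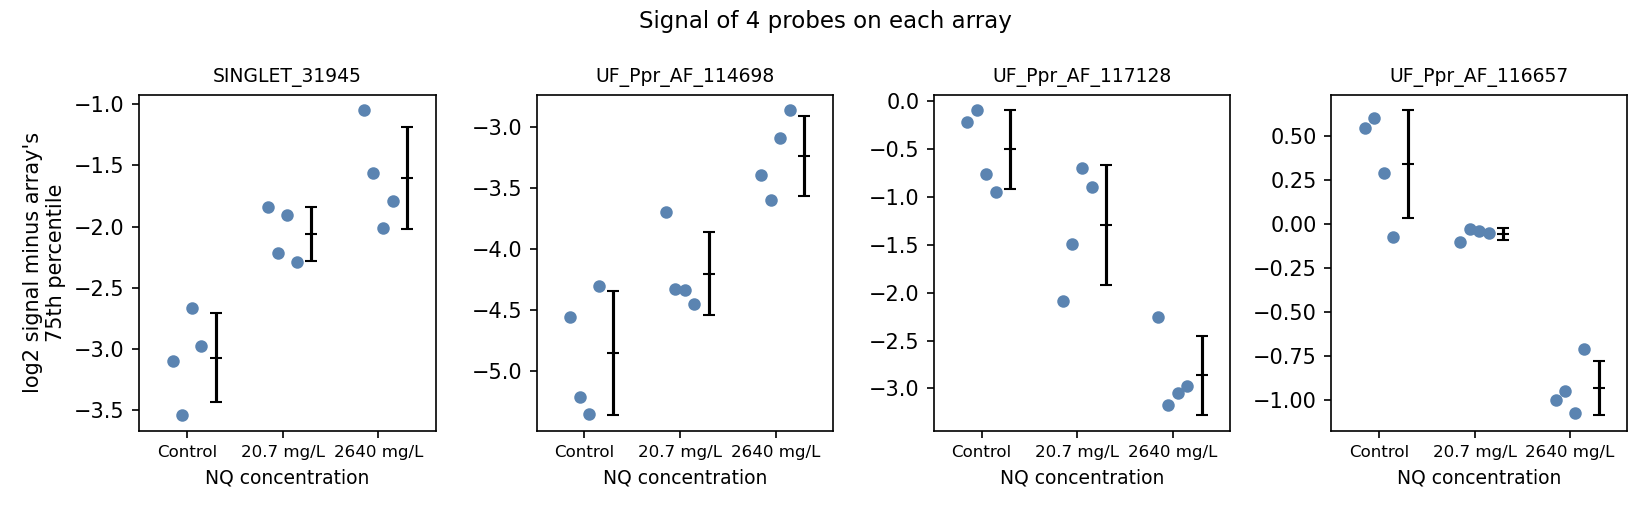
Log2 signal relative to the array's 75th percentile (vertical axis, log2 units) for 4 probes in the control, 20.7 mg/L and 2640 mg/L groups (horizontal axis). Points are single arrays (4 per group), and the black bars give mean ± SD. The probes were picked for their small p between 2640 mg/L and control. The 4 arrays at 2640 mg/L lie apart from the 4 control arrays for each probe, none of which passed the adjusted test.

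The distance between whole arrays passed its test with all 8 arrays, but not under several alternatives. It also passed with quantile normalization and the authors' table (exact permutation p = 0.0286 each). Median centring shifts each array by a constant and so cannot change this distance. The authors' values, centred per probe, gave 0.137, a size that cannot be set against the others. The mean correlation distance between 2640 mg/L and control arrays exceeded that within the groups by 0.00605 (exact permutation p = 0.0286, the smallest that 35 splits allow; Benjamini-Hochberg adjusted over 3 comparisons 0.0429). Leaving out any of 7 of the 8 arrays ended this call (exact permutation p = 0.0571 to 0.371, where 7 arrays allow 0.0286). Apart from 2640 mg/L replicate 1, the distance then stayed near its full value, at 0.00577 to 0.00700. Normexp background correction (0.00120, exact permutation p = 0.343) and keeping dim probes (0.00261, exact permutation p = 0.0571) also ended the call. Without 2640 mg/L replicate 1 the difference was 0.000851 (exact permutation p = 0.371), and the number of probes at an unadjusted p under 0.05 fell from 4287 to 2878. Arrays at 2640 mg/L lay mostly in the inner columns of their slides (3 of 4) and control arrays mostly in the outer ones (3 of 4). With inner or outer column as a block the number was 3949; that fit compares 1 control array with 3 exposed arrays in inner columns and 3 with 1 in outer ones. Normexp background correction gave 2241 probes, 34.5% of them higher at 2640 mg/L, against 52.5% with the processed signal and 45.4% with quantile normalization. Called probes numbered 2 with slide as a fixed block and 4 with array weights, and 0 with array weights and slide column as a block. The column block takes 2640 mg/L replicate 4, the only array in its column, out of the comparison. The fixed slide block likewise takes out 2640 mg/L replicates 1 and 3, each the only array from its slide.

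The comparison of 20.7 mg/L with the control asks whether the lowest concentration alters transcript signals. No probe of 31143 was called by limma, and the smallest adjusted p was 0.877. An unadjusted p under 0.05 was reached by 1239 probes (3.98%), 811 higher and 428 lower, fewer than the 1557 expected by chance. The share of these that were higher, 65.5%, depended on the scaling, at 48.5% with quantile normalization and 52.7% with median centring. With normexp, which changed the background correction and the spot signal, it was 55.6%. At least 2-fold differences were seen for 275 probes higher and 177 lower, and the groups did not overlap for 876 probes (2.81%, against 2.86% by chance). The distance between the groups was smaller than that within them by a difference of -0.00137 (exact permutation p = 0.686). The number at an unadjusted p under 0.05 was 2038 with slide as a fixed block, 2239 with array weights and 401 with normexp, again with 0 calls.

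The comparison between the exposed groups asks how the highest concentration differs from the lowest. No probe of 31143 was called by limma, the smallest adjusted p being 0.0517, and 4265 (13.7%) had an unadjusted p under 0.05, 1923 higher and 2342 lower at 2640 mg/L. The share higher was 45.1%, against 51.9% with median centring, 46.8% with quantile normalization and 34.5% with normexp. At an adjusted p under 0.10 there were 19 probes. At least 2-fold differences numbered 595 higher and 561 lower, and the groups did not overlap for 3162 probes (10.15%, against 2.86% by chance). The distance between the groups exceeded that within them by 0.00710 (exact permutation p = 0.0286, adjusted 0.0429), and without 2640 mg/L replicate 1 by 0.00291 (exact permutation p = 0.171). That call was also lost with normexp (0.00181, exact permutation p = 0.257) and with dim probes kept (0.00254, exact permutation p = 0.0571). Without 20.7 mg/L replicate 3 it was lost too (exact permutation p = 0.0571), although the distance was larger, at 0.00794. For UF_Ppr_AF_117128, UF_Ppr_AF_116657, SINGLET_31945 and UF_Ppr_AF_114698 the log2 differences were -1.57 (SE 0.33), -0.87 (SE 0.18), 0.46 (SE 0.25) and 0.97 (SE 0.27), none of them called. Array weights led to 442 calls, 174 of them higher at 2640 mg/L. Every array in an inner slide column had a higher weight than any array in an outer one. In the 20.7 mg/L group, replicate 3, its 1 inner-column array, had 2.81, against 0.646 to 0.788 for the others. The lowest weight, 0.339, went to 2640 mg/L replicate 1, but leaving that array out, without weights, gave 0 calls. The weighted calls therefore do not tell slide place from exposure. Array weights led to 0 calls once slide column was a block as well, which takes 2640 mg/L replicate 4 out of the comparison. Inner or outer slide column as a block led to 2 calls.

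**Figure D2:**
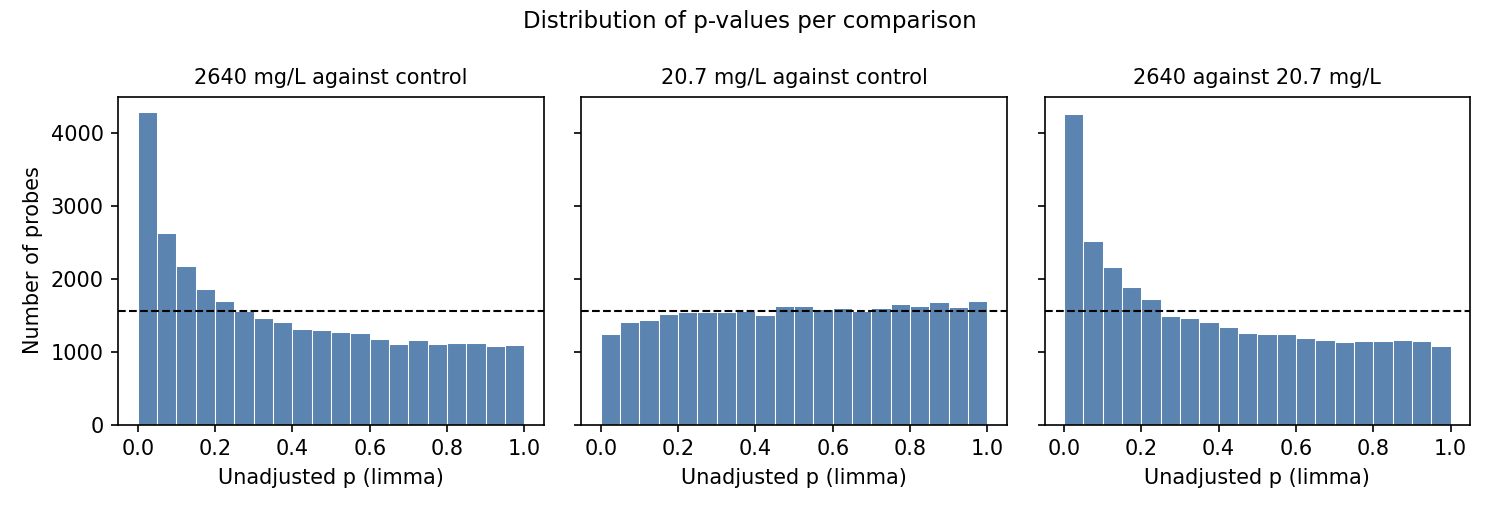
Number of probes (vertical axis) per bin of 0.05 of unadjusted limma p (horizontal axis, 0 to 1) for the 3 comparisons of 31143 probes. The dashed line is the number per bin expected with no difference; the first bin holds 4287 probes for 2640 mg/L against control, 1239 for 20.7 mg/L against control and 4265 between the exposed groups.

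Both exposed groups were set against the same 4 control arrays, which by itself makes their differences alike. Across probes, which are not independent replicates, log2 differences from the control at 20.7 and 2640 mg/L correlated with r = 0.368, against 0.5004 in simulated unchanged groups sharing the controls. Their covariance was 0.0590 against 0.0661 in the simulation, a difference of -0.00713. The simulated arrays were independent and equal in spread. The real arrays had weights from 0.339 to 2.81 and shared deviations by slide place. Values below the simulation are therefore no evidence about the responses. With the controls split so that each concentration had its own 2 control arrays, r lay between -0.137 and 0.0493. Probes at an unadjusted p under 0.05 in both comparisons numbered 227 higher in both (179.8 in the simulation, 58.6 for independent lists), 112 lower in both (181.7 and 28.0), and 28 with opposite signs.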

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

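Tests of slide column, of single slides, of the left-out array, of beaker number, of signal strength and of the spike-in ratio were chosen after the results they bear on were seen; the splits of 8 arrays, on a count added after the data were seen, and the test of paired spots were set out before their own results were seen.

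Dixon's outlier test for 4 values singled out 3 of 33 groups of arrays, where chance gives about 1 in 20. On the first principal component, 2640 mg/L replicate 1 lay at 119.5 with its nearest neighbour at 22.2. On the same component 20.7 mg/L replicate 4 lay at -34.9, with the nearest of its group at -10.9. The signal of UF_Ppr_AF_114698 in 20.7 mg/L replicate 1 was -3.70 on the log2 scale, against -4.33 for the nearest array of its group.

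Only 1 of the 35 splits of the 8 arrays, the real one, reached the excess of small p-values between 2640 mg/L and control (4287 probes). The highest other split gave 2777. A share of 1 in 35 is the smallest that these splits allow, so chance assignment of the arrays is unlikely but not excluded. Without 2640 mg/L replicate 1, however, 2 of the 35 splits of 7 arrays gave as many as the real 2878, and the other one gave 3313; it grouped control replicate 3, which like the remaining 2640 mg/L arrays lay in an inner slide column, with them. With slide column as a block the number was 4136, but with array weights added it fell to 2052 (under 1.5 times the 1557 expected), in a fit that gave replicate 1 the lowest array weight, 0.274. A column block also takes 2640 mg/L replicate 4, the only array in column 3, out of the comparison. The fall therefore cannot be put down to slide place. The place on the slide cannot be fully told apart from exposure, because 3 of 4 arrays at 2640 mg/L lay in inner columns and 3 of 4 controls in outer ones. Replicate 1 was the only array at that concentration in an outer column. With inner or outer column as a block the number was 3949. The outer columns differed from each other: the log2 spike-in ratio (below) was 2.09 to 2.24 in column 1 and 2.44 to 2.61 in column 4. An effect of NQ stays open as a hypothesis, and so does a contribution of replicate 1 and slide place.

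For 2640 mg/L against 20.7 mg/L, 1 of 35 splits, the real one, reached 4265 probes and the highest other gave 2536. This is the smallest share that 35 splits allow, so chance assignment of the 8 arrays is unlikely but not excluded. The imbalance of slide places was the same (3 of 4 arrays at 20.7 mg/L in outer columns). Without 2640 mg/L replicate 1, 2 of the 35 splits of 7 arrays gave as many as the real 3351, the other one 3496, so that chance is not excluded for the remaining arrays. For 20.7 mg/L against control, 22 of 35 splits gave as many as the real 1239, so chance cannot be excluded. The highest of those, 4842, parted the 4 arrays in slide column 1 from the other 4, a structure of the samples by slide place and not by exposure. With slide column as a block, the 20.7 mg/L comparison gave 1389.

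Arrays in one slide column shared deviations from their group means: the mean correlation across probes was 0.102 for 14 pairs in one column and -0.0419 for 34 pairs in different columns (one-sided exact permutation p = 0.0133, adjusted over 4 overlapping tests 0.0440). The 2 pairs that also shared a slide had a mean of 0.389, and the 12 pairs on different slides only 0.0541 (SD 0.0807), against -0.0533 for pairs sharing neither (exact permutation p = 0.0220, adjusted 0.0440). The ratio of 2 spike-in control probes, which carry no larval RNA, also differed between columns (exact permutation p = 0.000180; 0.00180 adjusted over the 10 pairs of bright spike-in probes, of which 3 passed and this one had the largest share of variance between columns), and did not separate the exposure groups (permutation p = 0.603). This is in line with handling, such as hybridisation or washing, that differed across the slide, which may have shaped the larval signals as well. Arrays sharing a beaker number in different columns had a mean correlation of -0.0708 (SD 0.148, 6 pairs), which argues against beaker number, whereas arrays sharing a slide deviated together (mean difference 0.150, exact permutation p = 0.0356, adjusted 0.0475) mainly through the pairs that also shared a column, the 5 in different columns having a mean of 0.0238 (SD 0.0731); deviations from group means hold no exposure difference, so no biological explanation was tested.

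The distance of 2640 mg/L replicate 1 from its group was not local spot noise alone, since its deviations in the 2 spots of 6004 probes correlated with r = 0.515 (0.305 to 0.653 for the other arrays). That value lies within the range of the other arrays, so spot noise is not ruled out as a part of it. Weaker labelling is argued against by 3 arrays with a 75th percentile signal below its 577.9 and a narrower spread, at most 0.54 against 0.84. Its deviation had little relation to that of slide column 1 in the control and 20.7 mg/L groups (r = 0.143). It was the only array here from its slide, so an effect of that slide could not be separated from a difference between beakers, and both stay open and untested.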

How the results depend on the processing

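Normexp on median signals, all settings for slide column or row, the counts at an unadjusted p and the distances were chosen after the data were seen. Calls at 20.7 mg/L against control stayed at 0 under all 34 alternatives; at 2640 mg/L they were 0 under 32 of 34 and against 20.7 mg/L under 28. The cause was not tested unless stated.

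Normexp gave 2241, 401 and 2466 probes at an unadjusted p under 0.05 (2640 and 20.7 mg/L against control, then 2640 against 20.7 mg/L), and distances of 0.00120 and 0.00181 for 2640 mg/L against control and 20.7 mg/L, neither passing. With no filter on dim probes these distances were 0.00261 and 0.00254, also not passing. Slide as a fixed block gave 2 calls at 2640 mg/L against control, 2038 probes at an unadjusted p under 0.05 at 20.7 mg/L, and r = 0.545 between the concentrations' responses. That fit takes 2640 mg/L replicates 1 and 3 out of the comparisons at that concentration. Slide as a random block gave 4 calls between exposed groups, and an adjusted p under 0.10 gave 19. Array weights gave 4 calls at 2640 mg/L against control, 442 against 20.7 mg/L and 2239 probes at an unadjusted p under 0.05 at 20.7 mg/L against control. With them, 3 of the 4 named probes passed. These weights were higher for every array in an inner slide column than for any array in an outer one.

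Slide column as a block gave r = 0.265, and with array weights r = 0.218 and 2052 probes at an unadjusted p under 0.05 at 2640 mg/L against control. Column 1 alone (only replicate 1 at 2640 mg/L, spread from the other groups) gave r = 0.259, with 4808 and 4685 probes at an unadjusted p under 0.05 at 2640 mg/L against control and 20.7 mg/L. Column 2 alone (1 control, 1 at 20.7, 2 at 2640 mg/L, lone arrays likewise) gave 1625 and 2622. Inner or outer column as a block gave 2 calls between exposed groups, and with 2640 mg/L replicate 1 left out 931 and 1437 such probes, and r = 0.274; that fit has 1 array of each other group in inner columns, so a fall is partly built in.

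Leaving out each array in turn gave 0 calls at 2640 and 20.7 mg/L against control and 0 to 1 between exposed groups (1 without 20.7 mg/L or 2640 mg/L replicate 4). Probes at an unadjusted p under 0.05 ranged from 2878 to 4400, 1024 to 1615 and 3345 to 4477, and r from 0.309 to 0.519. Distances ranged from 0.000851 to 0.00944 (exact p = 0.0286 to 0.371) for 2640 mg/L against control, 0.00291 to 0.00916 (exact p = 0.0286 to 0.171) against 20.7 mg/L, and -0.00260 to 1.73e-05, reversed without control replicate 3, for 20.7 mg/L against control.

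Replicate numbers did not pair the samples: same-numbered control and 20.7 mg/L arrays had correlations from -0.243 to 0.318. With the replicate number as a block there were 0 calls in each comparison and 4142, 1255 and 4073 probes at an unadjusted p under 0.05, with r = 0.368. Gene lists were not run (no gene names), nor distances with blocks, weights or other priors. Signal limits: 58.7% to 76.1% of probes lay well above background.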

Other observations

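The counts of probes present in one group and absent in another, the shares by probe family and the slide column term were chosen after the other results were seen. Probes well above background on all 4 arrays of one group and none of the other numbered 25 for 2640 mg/L against control (24 of them present at 2640 mg/L), 3 for 20.7 mg/L against control and 21 between the exposed groups. Other splits of the same 8 arrays gave as many or more often enough that none of these stood out (exact permutation p = 0.400, 1.00 and 0.429). The highest other splits gave 378, 311 and 148 such probes.

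Probes of the array's 4 identifier families had similar shares at an unadjusted p under 0.05 for 2640 mg/L against control: 13.2% of 6026 kept CONTIG probes, 13.9% of 14370 SINGLET probes, 13.9% of 10541 UF_Ppr_AF probes and 16.0% of 206 UF_Ppr_AM probes. No test of the difference between families was made.

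A term for slide column (1 to 4, linear) in the limma fit called 550 probes, 113 higher and 437 lower toward column 4. Of 100 shuffles of columns within groups, 1 called as many, the highest being 685 calls.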
